A study of Mus musculus with 6 samples.

How the data were processed

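Expression was measured on 6 Affymetrix-type mouse arrays, 1 per sample, from total RNA that was amplified as cDNA and labelled with biotin, per the labels' protocols. The deposited table holds 1 log2 expression value per probe set and array, and RMA made these values per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a set on the log2 scale. Its version, the chip definition and any filter are not given in the sources used here. The log2 unit of the deposited values was read from their range, their nearly equal medians and the mention of RMA, and scanner files were not used here. RMA forces the arrays onto a shared distribution, so a shift of most transcripts in one direction would be removed, and differences are compressed near the floor, where fold changes of dim transcripts are understated.

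The table held 45101 rows. The 64 control probe sets of the manufacturer were left out of the tests, which left 45037. The platform annotation paired 34945 of these with 1 gene symbol, 932 with several and 9160 with none, and no gene was named from a probe set with several. Gene identifiers of 34741 probe sets with 1 gene were found in a RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. That table was used for names and for which genes are neighbours, and no coordinates are given because no build is named for the array. The probe sets with 1 symbol covered 18193 genes, of which 9010 had more than 1 probe set. Each gene was read from the probe set with the highest mean over the 6 arrays, a choice that does not use the groups.

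Samples were grouped by their titles, 3 after withdrawal and 3 under doxycycline. Group means were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend or robust options, on all 6 arrays with no covariate, which left 4 residual degrees of freedom and 3.54 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over the 45037 probe sets, with a threshold of 0.05. The words rose and fell are used of genes past that threshold, and every adjusted p of a gene comes from limma.

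A set of 34 gene lists with 798 different genes, of which 736 were measured, was written from general knowledge. Camera of limma compared each list with the other genes, with the inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the 34 lists. Beside it, single genes were adjusted over the list alone, camera was run with an estimated correlation and fry was run. With an estimated correlation camera also rests on the 4 residual degrees of freedom, so a call lost there need not mean that the genes of a list are correlated. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes. The lists, the tests, the naming rule and the alternatives, except those said to be added later, were fixed before the data were examined.

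The genes named were Mecom, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with groups that do not overlap and a mean of at least 7 in the higher group, and in each list up to 4 members with the smallest adjusted p and up to 2 with the largest difference among those that did not pass. Symbols of unnamed transcripts were left out, and any member of a list of at most 12 genes may be named. Of lists without a call, mainly the passed members are named. Other passed members of the called lists, Kit, and the genes in the closing observations were named after their values were seen.

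The steps were tested on simulated data with the real probe set means and spreads, in which 200 of 45037 probe sets were changed. These 200 were drawn only from probe sets with a mean above the median, so recovery of dimmer ones was not tested. Of the 100 changed by 1 on the log2 scale 93% were recovered, and of the 100 changed by 0.5 45%. Of 141 calls 3 were false, which is 2.13%. A list moved by 0.3 was found, and 0 of 27 other lists were called. The simulated noise was independent between genes, whereas estimated correlations within the real lists reached 0.239. The simulation therefore does not test how often camera calls a list of correlated genes by mistake.

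The alternatives were each replicate left out in turn, the replicate number as a block, a filter on dim probe sets, arrays centred on their medians, a repeated quantile normalization, eBayes with trend and robust options, array weights, a fold threshold, the mean of a gene's probe sets, probe sets without shared or cross-hybridising names, and the other list tests. A pseudocount was not needed because the values are on a log scale. After the data were seen, a fit on 4 arrays and a fit with each array's interquartile range as a covariate were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.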

Results

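Gene expression was measured on 6 arrays in 1 clone of mouse haematopoietic progenitor cells, the myeloid clone C6. The clone carries a lentiviral vector in which doxycycline switches on a codon-optimized murine Evi1, a zinc finger transcription factor encoded by the Mecom locus, and the series description calls the clone dependent on Evi1. Cells were kept in medium with stem cell factor (50 ng/ml), interleukin 3 (20 ng/ml), Flt3 ligand (50 ng/ml) and interleukin 11 (50 ng/ml). The 3 arrays of the doxycycline group came from cells under 1 µg/ml doxycycline, and the 3 arrays of the withdrawal group from cells 48 h after the drug was removed. The single comparison, withdrawal against doxycycline, asks which transcripts differ once the inducer of Evi1 has been taken away. Each difference below is withdrawal minus doxycycline on the log2 scale, given with its standard error from limma over n = 3 arrays per group.

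The value distributions of the arrays were close, with medians from 5.23 to 5.27 and interquartile ranges from 3.71 to 3.92 on the log2 scale. On the 22518 brighter probe sets the first principal component held 47.7% of the variance and separated the groups, while the second held 31.9% and set withdrawal replicate 3 (score -22.99) and doxycycline replicate 1 (score -11.43) apart from the other arrays. Pearson correlations across probe sets ran from 0.995 to 0.998 within groups and from 0.994 to 0.996 between them, and no arrays held identical values. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

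**Figure D1:**
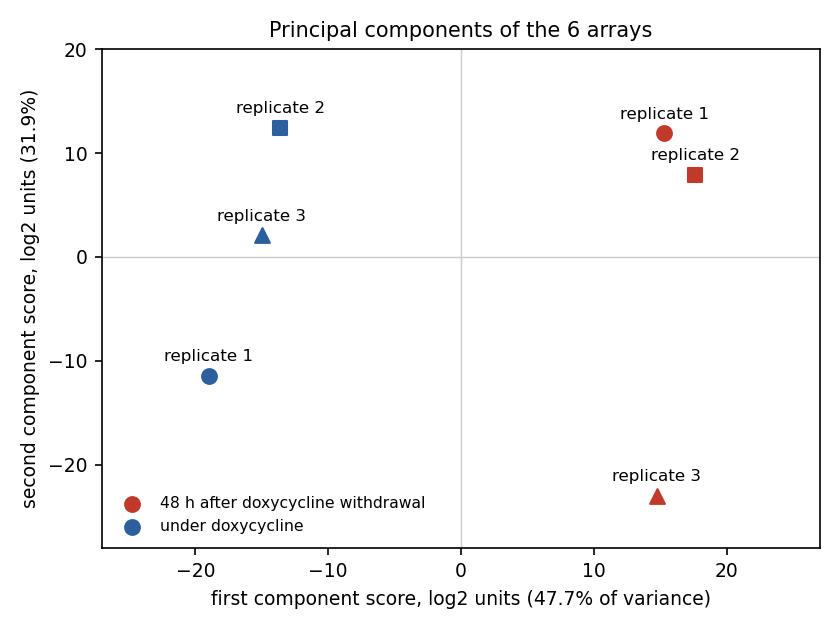
Scores of the 6 arrays on the first principal component (horizontal axis, 47.7% of variance) and the second (vertical axis, 31.9%), in log2 units, with colour for the group and symbol for the replicate number. The withdrawal arrays lie to the right and the doxycycline arrays to the left, with withdrawal replicate 3 at -22.99 on the second component.

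After doxycycline withdrawal, 8 of 17 measured genes on the early granule list and 6 of 8 eosinophil genes rose. The early granule list also holds transcription factor genes. In turn, 5 of 23 megakaryocyte genes, 4 of 21 red cell genes and 8 of 29 stem and progenitor genes fell. On the stem and progenitor list 1 gene rose. The ranks that follow are among genes that met the naming rule, with a mean of at least 7 in the higher group. The largest fall was that of Ctsj, a lysosomal cysteine protease best known from the placenta, from 9.27 to 3.54 on the log2 scale, a level near the floor of the arrays, so no exact fold is given. On the brightest probe set of each gene, the next was that of Selp, the adhesion molecule P-selectin of platelets and endothelium, which was 6.82-fold lower, and the largest rise was that of Slc26a3, a chloride and bicarbonate exchanger, which was 5.10-fold higher, followed by Sucnr1, the receptor for succinate, which was 3.78-fold higher. These ranks depend on that choice, since with the mean of each gene's probe sets Selp (-1.95) differed by less than Aldh1a1 (-2.40), and Slc26a3 (1.37) by less than Sucnr1 (1.92). The basophil protease Mcpt8, already among the bright transcripts at 12.20 ± 0.06 (SD, n = 3), reached 13.56 ± 0.004 (SD, n = 3), a 2.57-fold difference. Of 20 measured genes of cholesterol synthesis 6 rose and none fell, and of 26 interferon-induced genes 4 fell and none rose. When 1 array was left out these counts became 6 or 7 rises of early granule, 4 or 5 of eosinophil and 0 to 3 of cholesterol genes, and 3 to 5 falls of megakaryocyte, 2 to 4 of red cell, 2 to 5 of stem and progenitor and 2 to 4 of interferon-induced genes. Without both arrays apart on the second component, a choice made after seeing the data, 3 early granule, 1 eosinophil and 0 cholesterol genes rose. In that fit 3 megakaryocyte, 2 red cell, 1 stem and progenitor and 1 interferon-induced genes fell. All of these lists were called by camera, but only the calls of early granule and cholesterol genes held with an estimated correlation, at adjusted p = 0.0225 each. Those of eosinophil, megakaryocyte, red cell and interferon genes were lost at adjusted p = 0.117 with an estimated correlation, and that of stem and progenitor genes at adjusted p = 0.143 with an estimated correlation. The estimated correlation lay below the preset 0.01 on the megakaryocyte (-0.020), red cell (-0.023) and stem and progenitor (-0.0003) lists, so correlated genes do not account for those losses. It lay above 0.01 on the eosinophil (0.239) and interferon (0.044) lists.

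Evi1 itself was read by 3 probe sets named Mecom, all near the floor of the arrays. Their differences were -0.10 ± 0.13, -0.04 ± 0.07 and 0.13 ± 0.09, with limma adjusted p = 0.788, 0.881 and 0.615. The brightest had means of 3.55 after withdrawal and 3.66 under doxycycline, at the 21.1st percentile of all probe sets. Because the transgene is codon-optimized, probe sets made to the natural mRNA may not hybridise to its transcript, so these values do not check the labels.

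Of 45037 probe sets tested, 356 were higher and 530 lower after withdrawal at an adjusted p below 0.05 in limma. Counted by gene, with each gene read from its probe set of highest mean, 218 genes were higher and 286 lower among 18193. Among these 504 genes, 16 at least doubled and 50 fell at least to the same degree, and the median absolute difference was 0.54. Leaving out 1 array at a time gave 57 to 152 higher and 93 to 183 lower genes, with fewer lower genes by more than 1.5 times for each of the 6 arrays and fewer higher genes by as much for each except withdrawal replicate 3. Without both arrays that stood apart on the second component, a choice made after seeing the data, 22 genes were higher and 54 lower.

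Ctsj went from 9.27 ± 0.12 (SD, n = 3) under doxycycline to 3.54 ± 0.13 (SD, n = 3), a difference of -5.73 ± 0.10 in the deposited values (limma adjusted p = 1.09e-06), whose size is uncertain because the withdrawal level was near the floor. Selp differed by -2.77 ± 0.06 (limma adjusted p = 2.90e-06), and both its other probe sets were called in the same direction. The membrane protein gene Ms4a4b differed by -2.53, Aldh1a1, a retinaldehyde dehydrogenase, by -2.40 and Pglyrp2, an amidase that cleaves peptidoglycan, by -2.12. Hbb-y, an embryonic globin read by a probe set that can cross-hybridise with other globins, dropped by 1.86. Phlda2, an imprinted gene that limits placental growth, differed by -1.83 and Bex6 by -1.63. The growth factor gene Fgf3 differed by -1.58, Ms4a4c by -1.56, Zfpm1, a cofactor of GATA1, by -1.56 and Pdzk1ip1 by -1.50. The probe set of Ms4a4c can also cross-hybridise with related genes. The other probe set of Ms4a4b did not move in the same direction, and with the mean of each gene's probe sets the differences were -1.18 for Ms4a4b and -0.95 for Zfpm1, both still past the threshold.

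Slc26a3, on a probe set that can read more than 1 transcript, differed by 2.35 ± 0.09 (limma adjusted p = 3.51e-05), from 5.67 ± 0.09 (SD, n = 3) to 8.02 ± 0.12 (SD, n = 3). Sucnr1 rose by 1.92, Hal, which deaminates histidine, by 1.54 and Akr1c18, a steroid dehydrogenase that inactivates progesterone, by 1.49. Lipg, the endothelial lipase, had the widest spread among these genes, at 1.48 ± 0.26 (limma adjusted p = 0.0377), and its call was lost without any 1 of the 3 doxycycline arrays or without withdrawal replicate 1 or 2, with adjusted p up to 0.142 over the alternatives. Lin28a, which blocks maturation of let-7 microRNAs, rose by 1.23, and H3c7, a histone H3 gene, by 1.12. With the mean of each gene's probe sets the differences were 1.37 for Slc26a3 and 0.67 for Lin28a, both still past the threshold. The other genes with the largest rises belonged to the granule and mast cell lists, namely Mcpt8 (1.36), Nkg7 (1.32), Ms4a2 (1.16), Alox15 (1.14) and Cst7 (1.08). The calls of all 24 of these genes except Lipg were kept when any 1 array was left out.

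**Figure D2:**
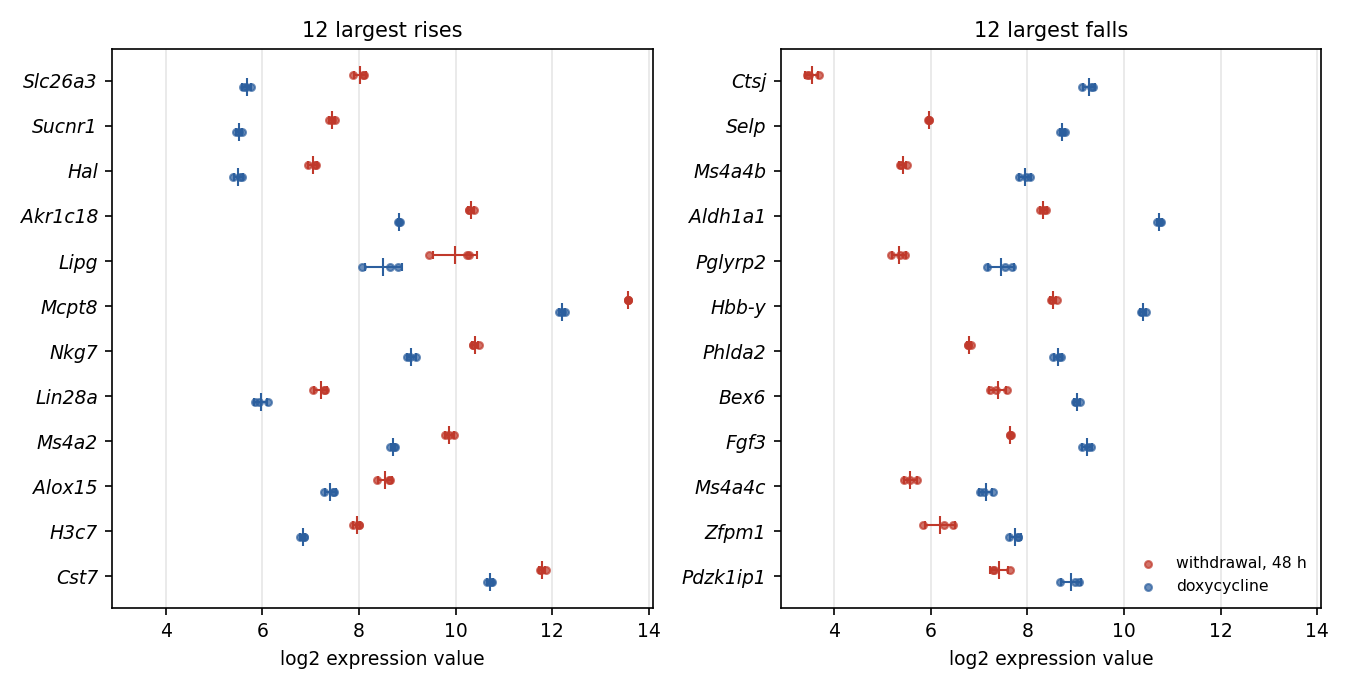
Deposited log2 expression values (horizontal axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) under the naming rule, with 1 point per array, a vertical tick at each group mean and a bar of 1 SD (n = 3). Ctsj shows the widest separation, at 3.54 after withdrawal and 9.27 under doxycycline, and Lipg the widest spread within its groups.

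On the list of genes of early, or primary, granules, 17 were measured, of which 8 rose, none fell and 9 did not pass; adjusted over the list alone, 12 rose. They were led by Nkg7, also a gene of cytotoxic lymphocytes, Cst7, which encodes cystatin F, Fcnb (0.83 ± 0.08) and Elane, the neutrophil elastase gene (0.74 ± 0.07). The transcription factors Cebpa (0.74 ± 0.07) and Gfi1 (0.54 ± 0.06), both needed for granulocyte development, were also among them. Mpo, the myeloperoxidase gene, differed by 0.32 with an adjusted p of 0.0580 and Ms4a3 by 0.29 with an adjusted p of 0.113, so neither passed. In camera this list had the smallest adjusted p of the 34 tested (1.83e-12), and its call held at adjusted p = 0.0225 with an estimated correlation. With 1 array left out, 6 or 7 of its genes passed. The remaining rises were those of Ctsg (0.32 ± 0.06, limma adjusted p = 0.0492) and Gstm1. The call of Ctsg was lost without any 1 of the 6 arrays. That of Gstm1 was lost without any 1 except withdrawal replicate 3 (adjusted p up to 0.235 and 0.165 over the alternatives).

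Of 8 measured eosinophil genes 6 rose and none fell; adjusted over the list alone, 6 rose and 1 fell. Alox15, a lipoxygenase, differed by 1.14 ± 0.10, the peroxidase gene Epx by 0.75 ± 0.07, the granule protein gene Prg3 by 0.74 ± 0.08 and the lectin gene Siglecf by 0.72 ± 0.08. Prg2, the major basic protein gene, rose by 0.44 and Il5ra, a subunit of the interleukin 5 receptor, by 0.54, from a dim 4.22 under doxycycline. Adgre4 (-0.48 ± 0.12) and Ccr3 (0.16 ± 0.09) did not pass. Only 4 or 5 genes of the list rose with 1 array left out, because the call of Il5ra was lost without any 1 of the 6 arrays and that of Prg2 without any 1 except withdrawal replicate 3 (adjusted p up to 0.142 and 0.148 over the alternatives). The list was called upward by camera (adjusted p = 7.84e-07), which was lost at adjusted p = 0.117 with an estimated correlation.

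Mast cell and basophil genes moved in both directions. Of 21 measured, 7 rose and 3 fell; adjusted over the list alone, 10 rose and 5 fell. Mcpt8 differed by 1.36 ± 0.06, Ms4a2, the beta chain of the high-affinity IgE receptor, by 1.16 ± 0.07, and the cytokine genes Il6 and Il4 by 0.94 ± 0.06 and 0.87 ± 0.08. Hdc, the enzyme that makes histamine, rose by 0.66, Rgs1 by 0.54 and Cd200r3 by 0.54. The genes that fell were Mcpt2, a protease of mucosal mast cells (-0.99 ± 0.13, with a withdrawal level of 4.32 near the floor that leaves the size uncertain), Slc18a2, a vesicular monoamine transporter (-0.70 ± 0.09), and Gzmb, granzyme B (-0.35 ± 0.06). Without doxycycline replicate 1 or 3 none of these 3 falls passed, and the call of Gzmb was lost without any 1 of the 6 arrays. The call of Rgs1 was lost without any 1 of the doxycycline arrays and that of Cd200r3 without any 1 array except withdrawal replicate 3. Mitf (-0.26) and Kit (0.26) did not pass. Camera called the list upward (adjusted p = 0.00172), and this was lost at adjusted p = 0.117 with an estimated correlation.

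The list of late neutrophil genes held 25 measured members, of which 2 rose and none fell; adjusted over the list alone, 3 rose and 1 fell. Trem3 differed by 0.74 ± 0.08 and Camp, the cathelicidin gene, by 0.35 ± 0.06, while Anxa1 (0.31 ± 0.06) and Mmp8 (-0.30 ± 0.06) did not pass. The call for Camp was lost without any 1 of the 6 arrays, with adjusted p up to 0.228, so 1 gene of the list rose in each of these fits. With trend and robust options 9 genes of the list rose and 1 fell, and above the median level 4 rose and 1 fell. The upward call in camera (adjusted p = 0.0246) was lost without withdrawal replicate 1 (adjusted p = 0.116) or doxycycline replicate 1 (adjusted p = 0.0537). It was also lost at adjusted p = 0.312 with an estimated correlation.

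Of 23 measured megakaryocyte and platelet genes, 5 fell and none rose; adjusted over the list alone, 8 fell and 3 rose. Beside Selp and Zfpm1, the chemokine genes Ppbp and Pf4, whose proteins platelets store in their granules, differed by -1.71 ± 0.16 and -0.59 ± 0.07, and Gp9, a subunit of the von Willebrand factor receptor, by -0.67 ± 0.11. Ppbp was at 4.12 after withdrawal, near the floor, so the size of its fall is uncertain. Itga2b, the platelet integrin alpha chain (-0.35 ± 0.08), and Gata1 (-0.36 ± 0.10) did not pass. With 1 array left out, 3 to 5 genes of the list fell, the smallest number without doxycycline replicate 2 or 3, when the call of Pf4 was lost (adjusted p up to 0.0737 over the alternatives). The call of Gp9 was lost without any 1 array except withdrawal replicate 3 (adjusted p up to 0.132 over the alternatives). The list was called downward by camera (adjusted p = 0.00172), which was lost at adjusted p = 0.117 with an estimated correlation.

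Red cell genes showed 4 falls and no rises among 21 measured; adjusted over the list alone, 8 fell and 2 rose. Rhag, the Rh-associated glycoprotein of the red cell membrane, differed by -2.22 ± 0.13, Hemgn by -1.14 ± 0.08, the water channel gene Aqp1 by -0.88 ± 0.13 and the carbonic anhydrase gene Car2 by -0.59 ± 0.07. Rhag and Aqp1 were dim after withdrawal, at 4.62 and 4.96, which leaves the sizes of their falls uncertain. Klf1, a transcription factor of the red cell lineage, differed by -0.48 ± 0.10 (adjusted p = 0.0570) and Alas2, an enzyme of haem synthesis, by 0.37 ± 0.09, so neither passed. The call of Aqp1 was lost without any 1 of the doxycycline arrays and that of Car2 without replicate 3 (adjusted p up to 0.102 and 0.0753 over the alternatives), so that 2 genes of the list fell without that array. The downward call in camera (adjusted p = 0.00601) was lost at adjusted p = 0.117 with an estimated correlation.

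Among 29 measured genes of stem and early progenitor cells, 8 fell and 1 rose; adjusted over the list alone, 10 fell and 3 rose. The transcription factor genes Sox4 (-1.23 ± 0.07), Tal1 (-0.66 ± 0.06), Mycn (-0.43 ± 0.07) and Lmo2 (-0.42 ± 0.06) fell. So did Myct1 (-0.71 ± 0.12), Angpt1 (-0.59 ± 0.07), Procr (-0.56 ± 0.10) and the surface antigen gene Cd34 (-0.51 ± 0.10). Prom1, which encodes the surface antigen CD133, rose by 0.68, and Slamf1 (-0.48 ± 0.11) and Hlf (0.30 ± 0.07) did not pass. With 1 array left out, 2 to 5 genes of the list fell. The calls of Mycn and Procr were lost without any 1 of the 6 arrays (adjusted p up to 0.215 and 0.170 over the alternatives), that of Cd34 without any 1 except withdrawal replicate 1, those of Lmo2 and Myct1 without any 1 except withdrawal replicate 3, and that of Angpt1 without doxycycline replicate 1 or 3 or withdrawal replicate 2. With the mean of each gene's probe sets Sox4 still passed at -0.38 and Myct1 at -1.66, and Mycn (-0.16) and Angpt1 (-0.33) did not pass. The downward call in camera (adjusted p = 0.0182) was lost at adjusted p = 0.143 with an estimated correlation.

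Of 31 measured monocyte and macrophage genes, 5 fell and 1 rose; adjusted over the list alone, 9 fell and 1 rose. Ms4a6c differed by -1.28 ± 0.06, Mpeg1 by -0.44 ± 0.06, Cd68 by -0.40 ± 0.06, Csf1r, the receptor of macrophage colony-stimulating factor, by -0.38 ± 0.06 and the complement gene C1qc by -0.37 ± 0.06. Fcgr3, an Fc receptor also present on basophils and mast cells, rose by 0.49. Irf8, a transcription factor of monocytes, differed by -0.53 ± 0.10 (adjusted p = 0.0537) and C1qb by -0.32 ± 0.12, and neither passed. Without any 1 of the arrays other than withdrawal replicate 3, only Ms4a6c fell (adjusted p up to 0.154 for Csf1r over the alternatives), and the rise of Fcgr3 was lost without any 1 of the doxycycline arrays or withdrawal replicate 2. With the mean of each gene's probe sets Ms4a6c still passed at -0.69 and Csf1r did not pass at -0.21. The downward call in camera (adjusted p = 8.62e-05) was lost at adjusted p = 0.162 with an estimated correlation.

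**Figure D3:**
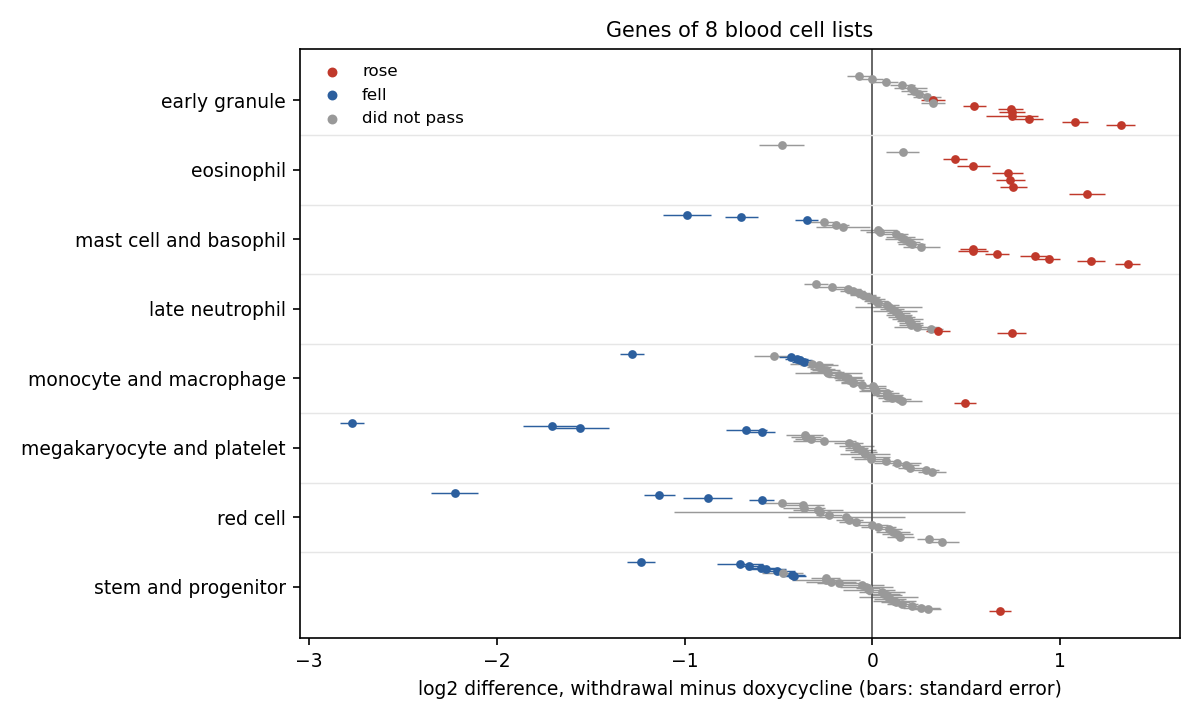
Log2 difference, withdrawal minus doxycycline (horizontal axis), of each measured gene on 8 blood cell lists, with a bar of 1 standard error and colour for genes that rose, fell or did not pass at an adjusted p below 0.05 in limma. The early granule and eosinophil lists hold 8 and 6 rises and no falls, and the megakaryocyte and red cell lists 5 and 4 falls and no rises.

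Of 20 measured genes of cholesterol synthesis 6 rose and none fell, and 19 of the 20 differences lay above 0; adjusted over the list alone, 15 rose. Dhcr7, which catalyses the last step from 7-dehydrocholesterol to cholesterol, differed by 0.77 ± 0.09, the demethylase gene Cyp51 by 0.51 ± 0.07, Mvd by 0.44 ± 0.07 and Nsdhl by 0.40 ± 0.07. Pmvk (0.47 ± 0.09) and Sc5d (0.36 ± 0.07) also rose, while Lss (0.42 ± 0.11) and Fdps (0.36 ± 0.09) did not pass. With 1 array left out, 0 to 3 genes of the list passed, with none left without doxycycline replicate 3. Nsdhl, Pmvk and Sc5d lost their call without any 1 of the 6 arrays, and Mvd without any 1 except withdrawal replicate 3. The call of Cyp51 was lost without any 1 of the doxycycline arrays or withdrawal replicate 2. With the mean of its probe sets Sc5d was at 0.22 and did not pass. The camera call (adjusted p = 3.93e-12) held at adjusted p = 0.0225 with an estimated correlation.

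Of 26 measured interferon-induced genes, 4 fell and none rose; adjusted over the list alone, 8 fell. These were the chemokine gene Cxcl10 (-1.22 ± 0.11), the guanylate-binding protein genes Gbp3 (-0.70 ± 0.09) and Gbp2 (-0.61 ± 0.07), and Xaf1 (-0.59 ± 0.10). Rsad2 (-0.44 ± 0.09, adjusted p = 0.0522) and Irf9 (-0.36 ± 0.07, adjusted p = 0.0608) did not pass. With 1 array left out, 2 to 4 genes of the list passed. The call of Gbp3 was lost without any 1 of the doxycycline arrays or withdrawal replicate 2, and that of Xaf1 without any 1 array except withdrawal replicate 1 (adjusted p up to 0.123 and 0.144 over the alternatives). Xaf1 was at -0.31 with the mean of its probe sets and did not pass. Camera called the list downward (adjusted p = 4.71e-05), which was lost at adjusted p = 0.117 with an estimated correlation.

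A further 4 lists were called by camera although none of their genes passed singly. Genes of ribosome biogenesis were lower, with 23 of 26 differences below 0 and none past the threshold adjusted over the list alone, and Gnl3 (-0.28 ± 0.06) and Polr1b (-0.24 ± 0.08) had the largest differences; the call (adjusted p = 0.000277) was lost at adjusted p = 0.429 with an estimated correlation. Chaperones of the endoplasmic reticulum were higher, with 17 of 18 differences above 0 and 5 rises adjusted over the list alone, among them Edem1 at 0.32 ± 0.07; the call (adjusted p = 0.000286) was lost at adjusted p = 0.117 with an estimated correlation. Genes of G2 and mitosis had 28 of 37 differences above 0, with Aurka at 0.28 ± 0.06 and Plk1 at 0.22 ± 0.08; the call (adjusted p = 0.00592) was lost at adjusted p = 0.480 with an estimated correlation and at adjusted p = 0.0533 without withdrawal replicate 1. Genes of S phase had 27 of 37 differences above 0, with Cdc25a at 0.33 ± 0.07 and E2f2 at 0.25 ± 0.08; the call (adjusted p = 0.0172) was lost at adjusted p = 0.480 with an estimated correlation, at 0.163 without withdrawal replicate 1 and at 0.0713 without doxycycline replicate 3. No gene of either cell cycle list passed adjusted over the list alone. With trend and robust options genes of these 4 lists did pass singly, with 5 falls of ribosome biogenesis genes and 5 rises of chaperone, 3 of G2 and mitosis and 2 of S phase genes.

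Of the genes that published work has named as targets of Evi1, 19 were measured, 2 rose and 3 fell; adjusted over the list alone, 2 rose and 4 fell. Cebpa (0.74 ± 0.07) and Serpinb2, a protease inhibitor (0.89 ± 0.09), rose. Adgrg1, an adhesion receptor also called Gpr56 (-0.90 ± 0.08, on a probe set that can cross-hybridise), Tal1 and Angpt1 fell, while Spi1 (0.27 ± 0.09) and Gfi1b (-0.29 ± 0.13) did not pass. The call of Angpt1 was lost without doxycycline replicate 1 or 3 or withdrawal replicate 2. The list as a whole was not called by camera (adjusted p = 0.749). Camera looks for a net shift in one direction, so rises and falls within this list can cancel.

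Single genes of other lists passed while their lists did not. Among cytokine signalling genes, Osm, which encodes oncostatin M, rose by 0.68, and Pim2, a survival kinase (-1.06 ± 0.10), Csf1r and Socs2 (-0.39 ± 0.07) fell; 1 of 22 rose and 3 fell, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.634). Among inflammatory genes Il6, Tnf (0.52 ± 0.08) and Ccl3 (0.46 ± 0.06) rose and Il18 (-0.78 ± 0.09) fell; adjusted over the list alone 3 of 24 rose and 3 fell (camera adjusted p = 0.708). Among immediate early genes Jun (0.53 ± 0.08) and Dusp1 (0.41 ± 0.07) rose and Spred1 (-0.49 ± 0.08) fell; adjusted over the list alone 4 of 27 rose and 1 fell (camera adjusted p = 0.112), and none of these genes passed without any 1 of the other arrays than withdrawal replicate 3, without which 3 genes rose, Spred1 did not pass and the list was called (adjusted p = 0.0225). Among adhesion and migration genes the cadherin gene Cdh1 (0.87 ± 0.08) and the chemokine receptor gene Cxcr4 (0.49 ± 0.08) rose and Selp and the integrin gene Itga4 (-0.37 ± 0.06) fell; adjusted over the list alone 6 of 25 rose and 3 fell (camera adjusted p = 0.519). Pdk1 (-0.48 ± 0.07) and Pfkp (-0.34 ± 0.06) fell and Ero1a (0.36 ± 0.06) rose among 24 genes of glycolysis and hypoxia, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.148). None of these 3 passed when 1 array was left out, except Pdk1 without withdrawal replicate 1. Likewise Socs2, Tnf and Itga4 lost their call without any 1 of the 6 arrays, and Csf1r, Ccl3 and Cxcr4 without any 1 except withdrawal replicate 3, with adjusted p up to 0.188 over the alternatives of these 6 genes. With the mean of each gene's probe sets Socs2 (-0.15) and Spred1 (-0.30) did not pass.

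Further lists without a call held 1 passed gene each, with 1 past the threshold adjusted over the list alone except where another count is given. These were Dnmt3b, a DNA methyltransferase (-0.69 ± 0.07), among 34 epigenetic regulators (camera adjusted p = 0.662), Bcl2, which protects from cell death (-0.40 ± 0.07), among 23 apoptosis genes (adjusted p = 0.519), Gadd45b (0.44 ± 0.08) among 23 cell cycle brakes (adjusted p = 0.708), Mycn among 10 G1 cyclin and Myc genes (adjusted p = 0.188, 1 rise and 2 falls adjusted over the list alone) and Atf5 (0.48 ± 0.08) among 24 genes of the Atf4 stress response (adjusted p = 0.475, 3 rises adjusted over the list alone). Except for Dnmt3b, each of these lost its call without any 1 of the 6 arrays, so the counts of their lists went from 1 to 0, with adjusted p up to 0.200 for Bcl2, 0.207 for Gadd45b, 0.215 for Mycn and 0.147 for Atf5 over the alternatives. With the mean of each gene's probe sets Bcl2 (-0.18) and Mycn (-0.16) did not pass either. Myc itself differed by -0.29 ± 0.06 and did not pass. None of the 22 genes of the response to transforming growth factor beta passed, and 4 fell adjusted over the list alone (camera adjusted p = 0.180). The lists of 34 nuclear genes of oxidative phosphorylation (adjusted p = 0.564), 28 lysosome genes (adjusted p = 0.611) and 22 p53 targets (adjusted p = 0.909) held no passed gene, and adjusted over the list alone 2 p53 targets rose and 1 fell.

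Markers of other cell types and of handling gave no call. Among 16 B lymphoid genes Cd79b, dim in both groups, fell (-0.57 ± 0.10) and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.480). Among 17 T and NK cell genes Nkg7 rose and Thy1 fell (-0.76 ± 0.07), also adjusted over the list alone (adjusted p = 0.909), and Thy1 was the single passed gene of 17 stromal genes by either adjustment (adjusted p = 0.708). None of 18 dendritic cell and class II genes passed by either adjustment (adjusted p = 0.475). On a list of 12 genes of RNA quality and dissociation stress (adjusted p = 0.519), Mt2 fell (-0.38 ± 0.06) and Malat1 was higher on its brightest probe set (0.39 ± 0.07) but lower on 2 others that passed, with the same counts adjusted over the list alone. The calls of Cd79b, Mt2 and Malat1 were lost without any 1 of the 6 arrays (adjusted p up to 0.217, 0.156 and 0.178 over the alternatives), which left no passed gene on the B lymphoid and RNA quality lists. Of the 64 control probe sets of the arrays 15 lay below all doxycycline arrays after withdrawal and 8 above, together more than the 10% that chance gives, and all 6 for the bacterial transcript dap were lower, by -0.68 to -0.20. Of all 18193 genes, 24.7% lay apart in one direction or the other. The median, mean and camera test differed in sign for adhesion (median 0.06, mean -0.02, test upward), stromal (median 0.04, mean -0.02, test downward), T and NK cell (median -0.01, mean 0.04, test upward) and p53 (median -0.02, mean 0.003, test upward) genes, none of them called by camera. Fry called the adhesion list downward (fry adjusted p = 0.0280).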

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

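The fits on 4 arrays and with the interquartile range as covariate were chosen after the data were seen. The 356 higher and 530 lower probe sets became 88 to 256 and 173 to 346 with 1 array left out, 862 and 1082 among probe sets above the median level, 1071 and 1389 with trend and robust options, 758 and 962 with array weights, 22 and 91 with at least a doubling or halving, and 28 and 94 on the 4 arrays. The 218 higher and 286 lower genes became 57 to 152 and 93 to 183 with 1 array left out, 498 and 580 above the median level, 634 and 732 with trend and robust options, 417 and 489 with array weights, 16 and 50 with the fold threshold, 22 and 54 on the 4 arrays, and 332 higher with the mean of a gene's probe sets. Fewer probe sets enter the filter and fewer arrays the fits without some of them. With the mean of a gene's probe sets, p-values were adjusted over 18193 genes in place of 45037 probe sets. Its counts and calls are therefore not directly comparable with those of the main fit. Otherwise the cause of these changes was not tested. Of the 14 lists called, 2 were called with an estimated correlation (early granules and cholesterol) and 12 by fry, which called 15 in all, with the adhesion, inflammatory and G1 cyclin lists besides. With 1 array left out 11 to 15 lists were called, the 15 without withdrawal replicate 3 being the same 14 and the immediate early list; the G2, S phase and late neutrophil lists also lost their call with the mean of a gene's probe sets, and the ribosome and S phase lists by fry. With the replicate number as a block, 94 probe sets were higher and 197 lower, and 63 genes were higher and 107 lower; the deviations of same-numbered arrays correlated at -0.304, 0.46 and -0.0326, so the numbers are not taken to pair the samples. Of 151 genes under the naming rule, passed or not, 17 to 34 lost their call with 1 array left out. Those that had not passed had no call to lose, so the share lost among the passed genes is larger than these numbers out of 151. Under the mean of its probe sets Malat1 reversed to -0.25, because its probe sets disagree, and fry called the adhesion list downward (mean -0.025), where camera leaned upward without a call. Median centring, repeated quantile normalization and the covariate kept the counts of all probe sets, genes and called lists within 1.5 times, but not all counts within single lists; for example, with the covariate 3 cytokine signalling genes rose in place of 1 and 2 Atf4 genes in place of 1, with quantile normalization 2 cytokine signalling genes, and with centring 1 glycolysis gene fell in place of 2. No detection calls were used here, so low signal over background limits what can be said of transcripts near the floor, such as Mecom.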

Other observations

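The tests on the array range, on doxycycline and on the spread of the megakaryocyte falls were chosen after the result was seen, and the genes in the first 2 paragraphs were picked after their values were seen. The Ms4a family of membrane proteins split by member. Of 17 measured genes, Ms4a2 rose (1.16 ± 0.07), 4 fell and 12 did not pass in limma. The falls were those of Ms4a4b (-2.53 ± 0.09), Ms4a4c (-1.56 ± 0.10), Ms4a6b (-1.48 ± 0.07) and Ms4a6c (-1.28 ± 0.06). Ms4a3 differed by 0.29 ± 0.07 and Ms4a6d by -0.26 ± 0.07 without passing.

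Some genes that lie next to each other changed in the same direction. Il4 rose by 0.87 and Il13 by 0.80, Osm by 0.68 and Lif by 0.66, and Dgat2 by 0.65 and Mogat2 by 0.61. Tal1 (-0.66) and Pdzk1ip1 (-1.50), Ppbp (-1.71) and Pf4 (-0.59), Aldh1a1 (-2.40) and Aldh1a7 (-0.86), and Tmem176b (-1.15) and Tmem176a (-0.94) fell. The call of Il13 was lost without any 1 array except withdrawal replicate 3, and that of Lif without doxycycline replicate 1 or 3 or withdrawal replicate 1 or 2.

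Over all genes, 24 adjacent pairs were called in the same direction, against a median of 8 when calls were shuffled 10000 times among genes of similar level (permutation p = 1e-04, the smallest these shuffles can give). Cross-hybridisation between gene copies could give such pairs; with pairs whose symbols share their first 3 letters left out, 13 remained against a 95th percentile of 12 and a median of 7 in the shuffles (permutation p = 0.0374, one-sided). A count above the 95th percentile had been set in advance as evidence against cross-hybridisation as the whole account; it was passed by 1 pair, less than the shuffles' SD of 2.69, and a requirement to exceed that SD was added after the count was seen. Some of the 13 pairs are still of related genes, such as Il4 and Il13 or Ppbp and Pf4, so cross-hybridisation and shared regulation of neighbours cannot be told apart here.

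On the mast cell and basophil, eosinophil, early granule, megakaryocyte and red cell lists 33 genes passed, all rises on the eosinophil and early granule lists, all falls on the megakaryocyte and red cell lists, and 7 rises and 3 falls on the mast cell and basophil list. One technical account is the range of values on each array, which varied from 3.71 to 3.92. With that range as a covariate the differences of these 33 genes kept a median of 1.01 times their size (lower quartile 0.986), and 32 were still called. The withdrawal arrays spanned 3.71 to 3.92 and the doxycycline arrays 3.82 to 3.88, so the range did not separate the groups. A ratio near 1 was therefore likely for any genes, and the fit with the covariate adds no evidence on this account. Another is that doxycycline acts on these genes without Evi1; no cells without the transgene are among the arrays, and the mean of the Atf4 stress list, 0.0431, bears only on mitochondrial stress, so loss of Evi1 and removal of the drug cannot be told apart.

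For the megakaryocyte genes, loss of a single cell type with all its transcripts falling by the same factor was tested. Selp and Pf4 were compared because theirs were the largest and smallest of the 5 falls, a choice that the standard error does not include. Selp fell by 2.18 ± 0.09 more on the log2 scale than Pf4 on its brightest probe set and by 1.36 ± 0.09 more with the mean of its 3 probe sets. Selp itself differed by -2.77 on its brightest probe set and by -1.95 with that mean. Probe sets of a single gene thus also gave unequal falls, so the comparison cannot decide whether the transcripts fell by one common factor. Whether fewer cells with such transcripts or lower expression per cell accounts for the falls stays open.

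Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split gave 886 probe sets, 504 genes and 14 lists, and was in each case the 1 split with as many. The highest of the other splits gave 0 probe sets, 0 genes and 3 lists. Several of the other splits also called 1 or 2 lists. Each of these splits is unbalanced between the groups, so part of the group difference can remain in such calls. They therefore do not show how often lists are called without a group difference. The other splits mix the groups, which puts the group difference into the spread within groups and makes calls of single genes unlikely.

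Ctsr, a neighbour of Ctsj in a cluster of placental cathepsins, fell by 1.05, with a level near the floor. Among the 64 control probe sets 15 lay below all doxycycline arrays after withdrawal and 8 above, where chance gives 10% in both directions together, although probe sets for one transcript are not independent. For comparison, 24.7% of all 18193 genes lay apart in one direction or the other. All 6 probe sets for dap, a bacterial transcript used as a spike-in, lay below, with a median difference of -0.30 as deposited and also lower after centring (-0.31) and repeated quantile normalization (-0.30), and 3 of 6 for thr did as deposited, 3 after centring and 2 after quantile normalization. None of the 14 probe sets for the bio transcripts lay apart in either direction, and all 3 for Gapdh lay above as deposited, 2 after centring. The labels do not say how spike-ins were added. Adjusted over the 64 controls, the middle part of 18S ribosomal RNA was lower after withdrawal (-0.28 ± 0.05, adjusted p = 0.0371 in limma) and so was the 5′ part of the DapX control (-0.50 ± 0.08, adjusted p = 0.0371).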
